A study of Mus musculus with 24 samples.

How the data were processed

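Polyadenylated RNA from interscapular brown adipose tissue (iBAT) of 24 mice aged 6 to 8 months was sequenced, per the labels. The animals fall into 4 groups of 6, each with 3 males and 3 females: wild-type (WT, C57Bl/6J) and Th-Cre mice, each given saline or deschloroclozapine (DCZ) 30 minutes before the tissue was taken. Th-Cre mice carry Cre recombinase under the control of tyrosine hydroxylase regulatory sequence, so that Cre acts in catecholamine-producing cells such as sympathetic neurons. DCZ is a ligand of muscarinic designer receptors. The receptor, the way it was delivered and the RNA integrity values are not given in the sources used here. Per the labels every library comes from a separate mouse, and the mouse numbers do not pair animals across groups.

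Per the submitters' processing notes, reads were processed with kallisto 0.44.0 and GRCm38.p6. The transcript set, the rule that summed transcripts to genes and the use of strand are not given in the sources used here, so reads of overlapping genes and of near-identical copies could be shared. The table analysed here holds estimated counts per gene symbol for all 24 libraries, deposited by the authors as whole numbers, and these estimated counts were tested as deposited. Total estimated counts ran from 11.9 to 22.9 M per library and lay within 205 reads of the deposited counts of pseudoaligned reads. The percent of reads that pseudoaligned, as deposited by the authors, was 84.2 to 88.7. Separate tables of normalized signal for each genotype were deposited by the authors, and checking them against the counts showed that each value is the count divided by 1 median-of-ratios size factor per library (0.802 to 1.13 in WT, 0.712 to 1.42 in Th-Cre). Genes with 20 or fewer reads over the 12 libraries of a genotype are absent from those tables, which hold 15570 genes in WT and 15488 in Th-Cre. That normalization was made separately in each genotype, so those values were used only within a genotype and only as an alternative.

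Of 36144 genes in the count table, 13364 had no read in any library. Genes with too few reads were removed with filterByExpr by group, which left 13129 genes that held 99.9% of all reads. Effective library sizes were set by the trimmed mean of M values (TMM), and counts-per-million values (CPM) below are on these sizes. Each gene was fitted with the edgeR 4.0.16 quasi-likelihood model (R 4.3.3) over all 24 libraries with a mean per group and a term for sex. For the interactions of sex and DCZ the model had 8 means, 1 for each sex in each group. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are said to have changed. The standard error (SE) of a log2 fold change is the size of the log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 15.6%. Symbols were matched to GENCODE M21 on GRCm38, where 99.4% of them (35933) were found, and coordinates are 1-based on that build. Every adjusted p without another method named comes from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

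The comparisons, the models, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. There were 28 tested lists: immediate early genes; acute cAMP and CREB targets; thermogenic and brown adipocyte identity genes; lipolysis and lipid uptake; fatty acid and triglyceride synthesis; glucose uptake and glycolysis; adrenergic signalling components; secreted factors of adipose tissue; circadian clock; glucocorticoid responsive genes; heat shock response; the unfolded protein and integrated stress response; inflammatory and NF-kB targets; nuclear oxidative phosphorylation; mitochondrially encoded mRNAs; and markers of skeletal muscle, erythroid cells, white adipocytes, endothelium, fibroblasts and preadipocytes, macrophages, lymphocytes, neutrophils, mast cells, smooth muscle and pericytes, Schwann cells, sympathetic neurons, and epithelial, thymic and gland tissue. A further list of sex-linked genes was used to check the labels. Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, with adjustment over the 28 lists. The same test with an estimated correlation and the fry test were alternatives. With the preset correlation many random splits of the libraries also gave called lists, as reported in the closing section, so such a call is described beside its value with an estimated correlation. A score per library is the mean log2 CPM of a list's genes, compared between groups of 6 by exact two-sided permutation over 924 arrangements.

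Named genes were, for each comparison, the 10 with the largest positive and the 10 with the largest negative log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and a symbol; the 5 with the smallest adjusted p; up to 4 members of each list with the smallest p; and always Th, Ucp1, Fos, Nr4a1, Per1, Dio2, Ppargc1a and Adrb3. Some are left out for length, and some are not reported here. Arl4d in Th-Cre mice, Dusp1, Jun and Ppp1r15a in WT mice and Chrm3 across all libraries were chosen after their values were seen. Of 128 calls on genes selected for naming, 24 were lost when a single library was left out and 49 were lost without 6 libraries that contain skeletal muscle transcripts. Counts of a list's changed genes that moved more than 1.5-fold on leaving out a single library are given with those libraries or left out, a choice made after the values were seen.

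The models were tested on simulated counts drawn from the means and spread of the real genes, with 200 genes changed. Genes were drawn independently of each other, and lowly expressed genes were not among those changed. The simulated libraries held no muscle content or library order, so the shares found hold only for counts without such structure. They also hold only for 200 changed genes. Where fewer genes change, the adjustment is stricter and smaller shares would be found. In the simulated Th-Cre DCZ against saline comparison (13042 genes) 71.6% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 95.5% of those changed 3-fold were found. In the simulated interaction of genotype and DCZ (13039 genes) the shares were 40.3%, 85.1% and 90.9%. In the simulated interaction of sex and DCZ they were 14.9%, 43.3% and 75.8% in Th-Cre (13044 genes), and 10.4%, 53.7% and 80.3% in WT (13033 genes). No libraries were duplicates: over 10282 genes with a mean of at least 50 reads, the smallest chi-square per degree of freedom of any pair was 5.57.

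Alternatives were RLE or upper-quartile factors, no filter or a filter of 5 CPM in 6 libraries, no term for sex, a robust fit, the compared groups alone, each sex alone, DESeq2 1.42.0, limma-voom with sample weights, the authors' normalized signal (limma on log2 of the value plus 1), and leaving out each library in turn. After seeing the data 3 more were added: leaving out the 6 libraries with skeletal muscle transcripts, the muscle score as a covariate, and offsets per library for GC content and transcript length. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.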

Results

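Transcript abundance was measured in interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades, from 24 mice that had received DCZ or saline 30 minutes earlier. Each of the 4 groups (WT saline, WT DCZ, Th-Cre saline and Th-Cre DCZ) held 6 mice, 3 of each sex. Total estimated counts averaged 16.1 M ± 2.14 (SD, n = 6) in WT saline, 17.9 M ± 1.34 in WT DCZ, 15.5 M ± 2.73 in Th-Cre saline and 16.8 M ± 3.56 in Th-Cre DCZ libraries. Mitochondrially encoded transcripts took 31.4 to 42.3% of the counts of a library. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d matched the labelled sex in all 24 libraries, with Ddx3y at 37.6 CPM or more in the 12 males and at 0.298 CPM or less in the 12 females. Th, the tyrosine hydroxylase gene whose regulatory sequence drives Cre (chromosome 7, 142892752 to 142931128, GRCm38), gave 1 read over all 24 libraries, so its level in the tissue was not detectable at this depth.

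Transcripts of skeletal muscle were unevenly spread over the libraries. The mean log2 CPM of 13 muscle markers was above 1 in 6 libraries: WT saline 12 (4.25), Th-Cre saline DN2087 (2.44), DN2094 (6.40) and DN2086 (4.94), and Th-Cre DCZ DN2075 (5.08) and DN2091 (1.83). In the other 18 libraries it was 0.0884 or lower. Of these 6 mice 4 were female. The counts of changed genes below, except those for the interactions of sex and DCZ, were therefore also taken without these 6 libraries, a choice made after the values were seen.

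**Figure D1:**
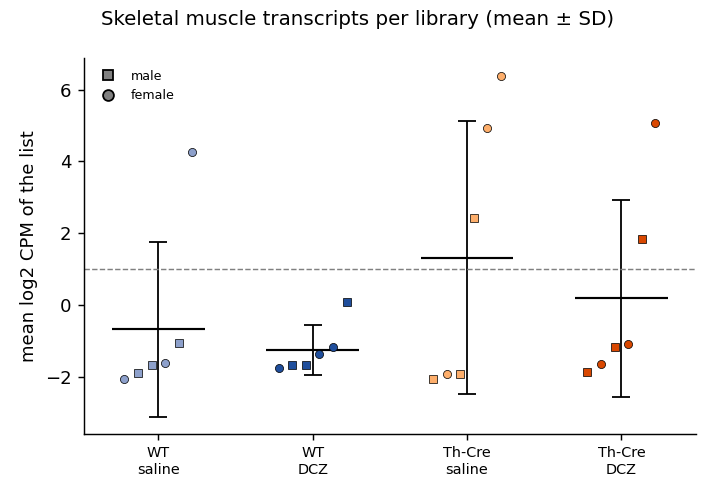
Skeletal muscle transcripts per library, as the mean log2 CPM of 13 markers, in the 4 groups (squares, males; circles, females; line and bar, mean ± SD of 6 libraries). The dashed line is at 1, and 6 libraries lie above it: 1 WT saline, 3 Th-Cre saline and 2 Th-Cre DCZ.

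The comparison of DCZ with saline in Th-Cre mice addresses the question in the series title, how chemogenetic activation of sympathetic neurons supplying this tissue affects it, here by transcripts at 30 minutes. Activity of the neurons was not measured here. Jun, Dusp1 and Ppp1r15a were higher after DCZ. Jun, a subunit of the AP-1 transcription factor, averaged 171 CPM ± 67.1 (SD, n = 6) after DCZ and 63.3 ± 27.2 after saline. The fitted rise was 2.68-fold (log2 fold change 1.42 ± 0.222 SE, adjusted p = 0.00514 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Dusp1, a phosphatase that inactivates MAP kinases, rose 2.42-fold from 69.4 CPM ± 9.63 to 168 ± 53.6 (1.27 ± 0.185, adjusted p = 0.00472). Ppp1r15a, which directs protein phosphatase 1 to the translation factor eIF2 alpha, rose 2.35-fold from 12.9 CPM ± 3.28 to 29.9 ± 7.29 (1.23 ± 0.186, adjusted p = 0.00472). All 6 DCZ libraries lay above the saline mean for each of these genes, and 5 (Jun, Dusp1) or 6 (Ppp1r15a) lay above every saline library. These were the only genes of 13129 past the threshold, and 745 had an unadjusted p under 0.05.

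On GRCm38, Jun lies on chromosome 4 (95049034 to 95052222, minus strand) and overlaps Junos on the other strand. Dusp1 lies on chromosome 17 (26505590 to 26562128, minus strand). It overlaps AC122252.1 and AC122252.4 on its own strand and Ergic1 and Gm8225 on the other. Ppp1r15a lies on chromosome 7 (45522916 to 45526268, minus strand) and overlaps Tulp2 on the other strand. These are overlaps of whole gene spans. Where transcripts share sequence, reads of neighbours on the other strand could not be told apart without strand. Strand would not separate neighbours on the same strand.

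Several further genes that catecholamines or growth signals are known to induce lay short of the threshold by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The nuclear receptor Nr4a1 had a log2 fold change of 1.39 ± 0.336 (SE, adjusted p = 0.162) with 282 CPM ± 67.1 after DCZ and 112 ± 35.2 after saline (SD, n = 6). For this gene 6 of 6 DCZ libraries exceeded every saline library. The growth arrest gene Btg2 stood at 1.40 ± 0.297 (adjusted p = 0.0874), and Gadd45b at 1.39 ± 0.321 (adjusted p = 0.136). The cAMP-induced kinase Sik1 stood at 0.98 ± 0.263 (adjusted p = 0.277) and Fos, the partner of Jun in AP-1, at 1.09 ± 0.434 (adjusted p = 0.73). Vamp1, a protein of vesicle fusion, had the lowest p among genes with a negative value, at -0.50 ± 0.094 (adjusted p = 0.0537). Genes of heat production and its control had adjusted p of 0.696 or more. Ucp1, which uncouples mitochondrial respiration, stood at -0.34 ± 0.126, with 2808 CPM ± 799 and 3505 ± 583. Values were -0.38 ± 0.185 for Ppargc1a, 0.22 ± 0.215 for Dio2, 0.41 ± 0.222 for Adrb3 and 0.40 ± 0.181 for the clock gene Per1.

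Among the lists, 27 of 28 immediate early genes had a positive value (median log2 fold change 0.87), 2 rose when adjusted over all genes and 23 rose when adjusted over the list alone. Over all genes 4 rose without Th-Cre DCZ DN2091. The camera test called the list at an adjusted p of 3.74e-26, with adjusted p = 0.109 with an estimated correlation and 0.0476 by fry. Of 21 acute cAMP and CREB targets, 17 were positive (median 0.45), 1 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 8.66e-09; adjusted p = 0.109 with an estimated correlation). This list shares 5 members with the immediate early genes, and the 16 others had a median of 0.25 (adjusted over 3 lists tested so, camera p = 0.000155; adjusted p = 0.0862 with an estimated correlation). Glucocorticoid responsive genes had a median of 0.28 with 17 of 18 positive and 5 risen adjusted over the list alone, against 1 over all genes, or 2 without Th-Cre saline DN2094 (camera adjusted p = 5e-07; adjusted p = 0.247 with an estimated correlation). Further camera calls were lost in the same way. Schwann cell markers had a median of 0.48 over 8 genes (adjusted p = 0.00468; adjusted p = 0.315 with an estimated correlation). Lipolysis and lipid uptake had 0.10 over 17 genes (0.0261; adjusted p = 0.247 with an estimated correlation). Macrophage markers had 0.19 over 11 genes (0.0325; adjusted p = 0.683 with an estimated correlation). Skeletal muscle markers had -1.08 over 13 genes (0.0261; adjusted p = 0.784 with an estimated correlation), and 3 of 6 saline and 2 of 6 DCZ libraries contained muscle transcripts.

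No call was made by camera for the other 21 lists, in which 0 genes changed when adjusted over all genes. Metabolic lists had medians near 0: thermogenic and brown adipocyte identity genes -0.03 (adjusted p = 0.189), fatty acid and triglyceride synthesis -0.03 (0.638), glucose uptake and glycolysis -0.03 (0.638), nuclear oxidative phosphorylation -0.03 (0.0525), mitochondrially encoded mRNAs -0.01 (0.944) and secreted factors of adipose tissue 0.12 (0.567). Adjusted over the list alone, Txnip (0.52 ± 0.111) and Pdk4 (0.48 ± 0.114), which restrain glucose uptake and pyruvate oxidation, passed within the glucose list. So did Sik1 within the adrenergic signalling components (median 0.01, 0.373). For heat shock genes the median was -0.06 and the mean 0.32 (0.703), with the chaperones Hspa1a (2.60 ± 0.71) and Hspa1b (2.69 ± 0.742), near-identical copies with uncertain counts, past the threshold adjusted over the list alone. Also past the threshold adjusted over the list alone were Angptl4 (0.47 ± 0.134) among lipolysis genes, Dnajb9 (0.48 ± 0.1) in the stress response list and Nrip1 (0.41 ± 0.136) among white adipocyte markers. The circadian clock had a median of -0.01 (0.744), the unfolded protein and integrated stress response 0.04 (0.119) and inflammatory and NF-kB targets 0.29 (0.0573). Cell type markers had medians of 0.52 for erythroid cells (0.323), 0.04 for white adipocytes (0.472), 0.05 for endothelium (0.416), 0.08 for fibroblasts and preadipocytes (0.416), -0.09 for lymphocytes (0.898), -0.09 for neutrophils (0.898), -0.30 for mast cells (0.415) and 0.17 for smooth muscle and pericytes (0.119). For sympathetic neurons 1 of 9 markers was tested (0.13, 0.638), and for epithelial, thymic and gland tissue 1 of 8 (0.06, 0.638).

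As a score per library, immediate early genes averaged 5.13 ± 0.386 log2 CPM (SD, n = 6) after DCZ and 4.31 ± 0.394 after saline, a difference of 0.82 (two-sided exact permutation p = 0.00866, adjusted over 4 scores 0.0173). Acute cAMP and CREB targets averaged 5.28 ± 0.181 and 4.79 ± 0.144, a difference of 0.49 (exact permutation p = 0.00216, the smallest that 924 arrangements can give, adjusted 0.00866). The thermogenic score differed by -0.07 (exact permutation p = 0.545) and the glucose score by -0.02 (exact permutation p = 0.766). The count of changed genes was 2 without the term for sex, where Jun (1.43) fell short, 4 with RLE or upper-quartile factors (3 higher and 1 lower in each), 12 by limma-voom and 37 by DESeq2. It was 18 without Th-Cre DCZ DN2091, 6 without Th-Cre saline DN2094, 5 without Th-Cre saline DN2087 and 5 without Th-Cre DCZ DN2207, with Jun, Dusp1 and Ppp1r15a among the calls each time a single library was left out. In 3 males against 3 no call on Jun, Dusp1 or Ppp1r15a was made (log2 fold changes 1.45, 1.21 and 0.99). In 3 females against 3 Dusp1 (1.34) and Ppp1r15a (1.47) passed and Jun (1.40) did not.

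**Figure D2:**
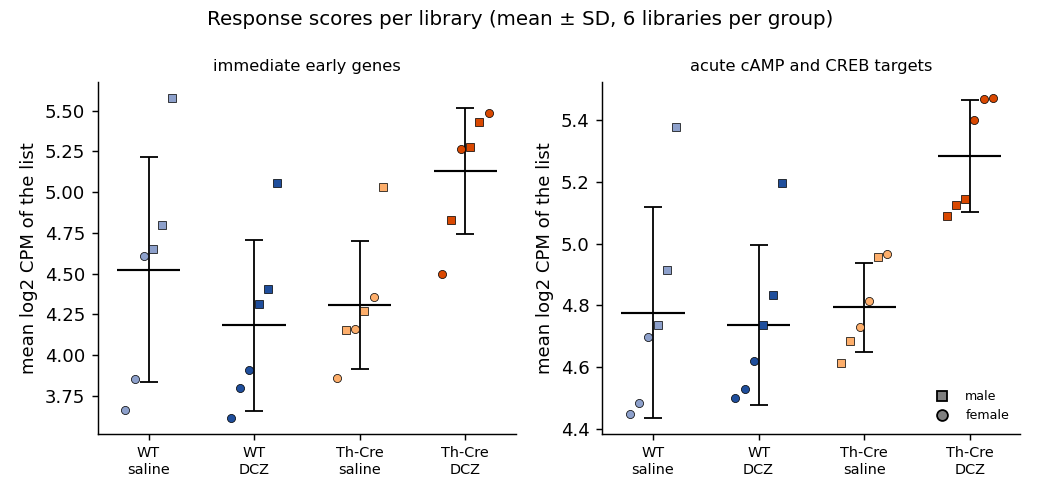
Mean log2 CPM of the immediate early genes (left) and of the acute cAMP and CREB targets (right) in each library of the 4 groups (squares, males; circles, females; line and bar, mean ± SD of 6 libraries). Th-Cre DCZ libraries average 5.13 and 5.28, and Th-Cre saline libraries 4.31 and 4.79.

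WT mice, which carry no Cre, were given DCZ as the control for effects of the ligand. Of their 6 lower library numbers 5 are DCZ and of the 6 upper ones 5 are saline, so treatment in WT mice is nearly confounded with library order. Arl4d, a small GTPase-like protein, was the only gene to change. It fell from 4.02 CPM ± 0.984 (SD, n = 6) after saline to 2.11 ± 0.393 after DCZ. Its log2 fold change was -0.93 ± 0.149 (SE, adjusted p = 0.0237 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with 6 of 6 DCZ libraries below every saline library. Arl4d lies on chromosome 11 (101665541 to 101667832, plus strand, GRCm38) and overlaps no other gene. The genes that rose in Th-Cre mice did not pass in WT: Jun stood at -0.13 ± 0.221, Dusp1 at -0.18 ± 0.183 and Ppp1r15a at -0.10 ± 0.185 (adjusted p of 0.776 to 0.887). Values for Fos (-0.81 ± 0.439), Nr4a1 (-0.48), Adrb3 (-0.29), Per1 (-0.10), Ucp1 (0.18), Ppargc1a (0.28) and Dio2 (0.34) had adjusted p of 0.596 or more. Next in p came Agk, a mitochondrial lipid kinase (0.40, adjusted p = 0.285), then Nsun3 (0.43), Slc25a17 (0.34) and Ncoa3 (-0.33), each at an adjusted p of 0.472.

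Of the immediate early genes 3 of 28 had a positive value in WT mice (median -0.46, camera adjusted p = 0.000509; adjusted p = 0.955 with an estimated correlation), and 0 of them passed the test over all genes. Camera also called thermogenic and brown adipocyte identity genes upward (median 0.15, 18 of 25 positive) and nuclear oxidative phosphorylation (-0.07) and endothelial markers (-0.18) downward, each at an adjusted p of 0.0259 and at an adjusted p = 0.955 with an estimated correlation. Acute cAMP and CREB targets had a median of -0.05 (camera adjusted p = 0.857). The immediate early score differed by -0.34 (two-sided exact permutation p = 0.355), by 0.41 within the lower and by -0.86 within the upper library numbers, each with 1 library on a side. Other scores differed less, the cAMP score by -0.04 (exact permutation p = 0.82) and the thermogenic score by 0.11 (exact permutation p = 0.106). The call on Arl4d was lost without any 1 of WT DCZ 1, 3, 4, 5 and 6 and WT saline 7, 8 and 9 (log2 fold changes of -0.95 to -0.83), and without WT saline 2 there were 39 changed genes. At 1137 genes with an unadjusted p under 0.05, DESeq2 called 2 genes, Arl4d not among them, and limma-voom 3. By edgeR 0 were called without a filter, without the term for sex, in WT libraries alone or in either sex.

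**Figure D3:**
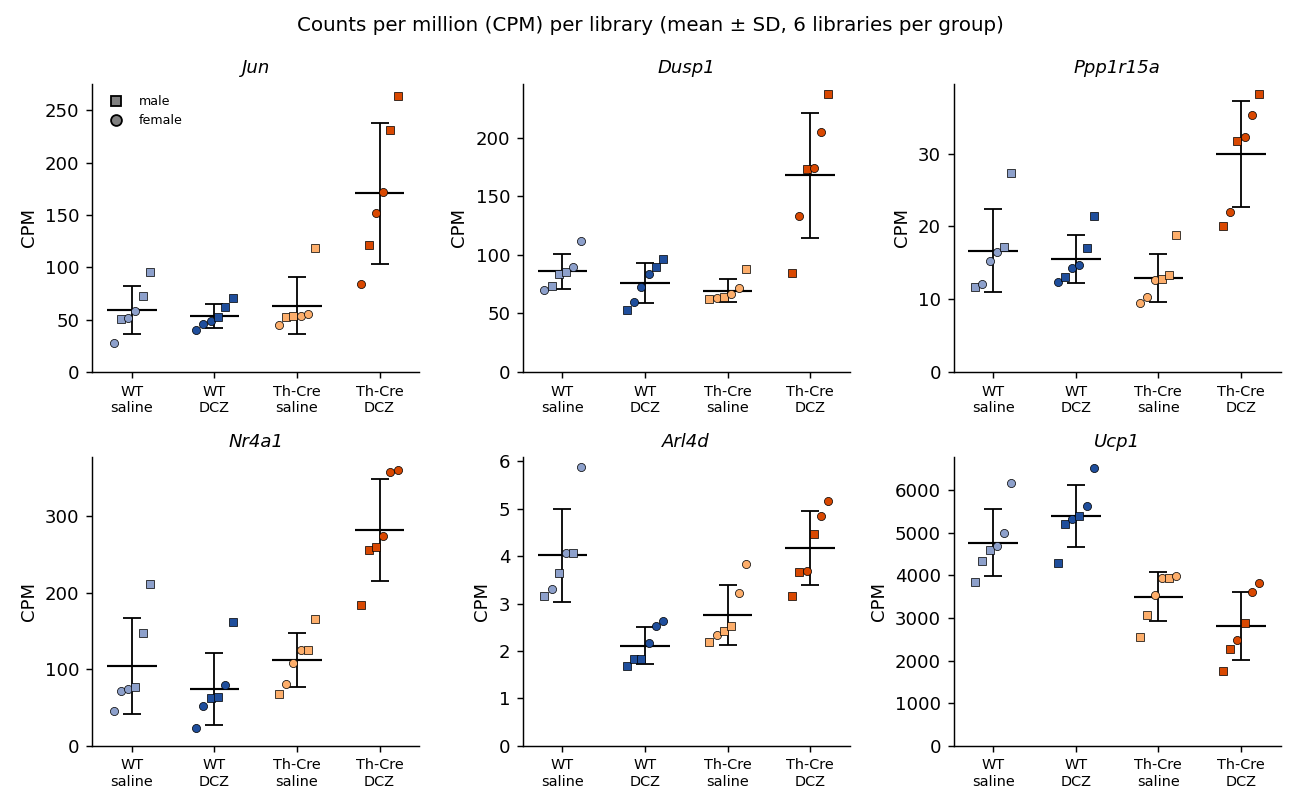
CPM of Jun, Dusp1, Ppp1r15a, Nr4a1, Arl4d and Ucp1 in each library of the 4 groups (squares, males; circles, females; line and bar, mean ± SD of 6 libraries; axes start at 0). Jun, Dusp1 and Ppp1r15a average 171, 168 and 29.9 CPM in Th-Cre DCZ libraries, and Ucp1 averages 2808 CPM there and 3505 CPM in Th-Cre saline libraries.

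Whether DCZ acted differently in the genotypes was tested as the interaction. Arl4d alone passed. It averaged 4.02 CPM in WT saline, 2.11 in WT DCZ, 2.75 in Th-Cre saline and 4.17 in Th-Cre DCZ libraries (n = 6 each). The log2 change with DCZ was higher by 1.53 ± 0.21 (SE) in Th-Cre mice (adjusted p = 0.00185 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its value within Th-Cre mice was 0.60 ± 0.147 (adjusted p = 0.164). Immediate early genes had large differences short of the threshold: Dusp1 1.45 ± 0.259 (adjusted p = 0.0571), Jun 1.56 ± 0.312 and Ppp1r15a 1.33 ± 0.262 (both 0.136), Arc 2.26 and Gadd45b 2.04 (both 0.147), Btg2 1.69 (0.305), Nr4a1 1.87 (0.333) and Fos 1.90 ± 0.618 (0.607). Values for the chaperone gene Dnajb1 (0.73, 0.147), Ucp1 (-0.52 ± 0.178, 0.607), Ppargc1a (-0.66, 0.607), Adrb3 (0.70, 0.643), Per1 (0.50, 0.688) and Dio2 (-0.12, 0.95) did not pass either.

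The order of the WT libraries enters this comparison too. As a list, immediate early genes had a median difference of 1.35, with 27 of 28 positive, 0 past the test over all genes and 21 risen adjusted over the list alone (camera adjusted p = 1.73e-23; adjusted p = 0.165 with an estimated correlation). For acute cAMP and CREB targets the median was 0.50, with 4 risen adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.639 with an estimated correlation). Their 16 members outside the immediate early list had 0.25 (camera adjusted p = 0.0133; adjusted p = 0.156 with an estimated correlation). Glucocorticoid responsive genes (0.44, 0.000175), inflammatory and NF-kB targets (0.76, 0.00521), endothelial markers (0.24, 0.0137) and Schwann cell markers (0.57, 0.0302) were called upward by camera and thermogenic and brown adipocyte identity genes downward (-0.16, 0.00521), all at an adjusted p of 0.728 or more with an estimated correlation. Skeletal muscle markers had a median of 1.97 while camera ranked them downward (0.561). Across all 13129 genes the DCZ responses of the genotypes had a Pearson r of 0.0143 (jackknife SE 0.222) and a Spearman rho of -0.0339, values across genes, which are not independent replicates. Arl4d passed without any single library (adjusted p of 0.000456 to 0.00626), while the count of genes rose to 7 without WT saline 2, 6 without Th-Cre DCZ DN2091, 4 without Th-Cre saline DN2087, 3 without WT saline 7 and 2 without WT DCZ 3 or Th-Cre DCZ DN2205. The stricter filter removed Arl4d and left 0 of 800 genes with an unadjusted p under 0.05, and DESeq2 called 16 genes.

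Th-Cre and WT mice given saline were compared to see what separates the genotypes before any ligand. There 3270 genes differed, 1643 higher and 1627 lower in Th-Cre mice. Ube2ql1, a ubiquitin-conjugating enzyme-like gene (chromosome 13, 69702832 to 69739889, GRCm38), had 20 CPM ± 7.39 (SD, n = 6) in Th-Cre and 1.37 ± 0.564 in WT mice. The fitted rise was 14.5-fold (log2 fold change 3.85 ± 0.47 SE, adjusted p = 7.99e-05 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The actin-assembling formin Diaph1 rose by 0.50 ± 0.0604 (adjusted p = 7.99e-05) and the oxysterol-binding protein Osbp by 0.55 ± 0.0719 (adjusted p = 0.000185). Among genes that fell were the kinase Ripk4 (-2.16 ± 0.386, adjusted p = 0.00126), the preadipocyte factor Dlk1 (-1.92 ± 0.35, adjusted p = 0.0014), the extracellular protein Nepn (-1.18 ± 0.155, adjusted p = 0.000185) and the interferon-induced GTPases Tgtp2 (-1.36 ± 0.328) and Gbp4 (-1.29 ± 0.264). In each of these genes all 6 Th-Cre libraries lay on the same side of the WT mean.

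Genes of lipid synthesis, of the respiratory chain and of blood vessels were among those that changed. Of 20 genes of fatty acid and triglyceride synthesis 9 rose and 1 fell over all genes, and 11 rose and 1 fell adjusted over the list alone (median 0.49, camera adjusted p = 0.011; adjusted p = 0.826 with an estimated correlation). Over all genes 4 rose without WT saline 9 and 5 without WT saline 12 or Th-Cre saline DN2099, DN2087 or DN2094, and 0 fell without WT saline 7, 8, 9 or 11 or Th-Cre saline DN2201, DN2099, DN2087, DN2094 or DN2086. The list included the desaturase Scd1 (0.98 ± 0.272, a call lost by DESeq2 at 0.99), the elongase Elovl6 (0.83 ± 0.189), the phosphatidate phosphatase Lpin1 (0.73 ± 0.144) and the acetyl-CoA carboxylase Acacb (0.46 ± 0.124). Of 36 nuclear genes of oxidative phosphorylation 24 fell and 2 rose, and 27 fell and 2 rose adjusted over the list alone (median -0.25, camera adjusted p = 1.32e-08; adjusted p = 0.679 with an estimated correlation). With offsets for GC content and length its median was -0.21 with 24 fallen, and without the muscle libraries -0.29 with 1 fallen. Ribosomal protein transcripts took 0.810% ± 0.0576 (SD, n = 6) of the counts in Th-Cre and 1.08% ± 0.134 in WT saline libraries, and GC content and length accounted for 6.73% of the variance of the log2 fold changes across genes. The list included the complex I subunits Ndufa1 (-0.63 ± 0.0998) and Ndufa2 (-0.69 ± 0.129) and the cytochrome oxidase subunit Cox6c (-0.54 ± 0.101). Endothelial markers fell in 7 of 10 cases over all genes and 8 adjusted over the list alone, as with Eng (-0.86 ± 0.158) and Emcn (-0.70 ± 0.13). That list had a median of -0.45 (camera adjusted p = 0.000294; adjusted p = 0.687 with an estimated correlation). Smooth muscle and pericyte markers fell in 5 of 8 cases over all genes and 6 adjusted over the list alone, as with Myh11 (-0.67 ± 0.127) and Tagln (-0.75 ± 0.145). Their median was -0.34 (camera adjusted p = 0.00204; adjusted p = 0.652 with an estimated correlation). As scores per library 0 of 13 marker lists passed the exact permutation test. The endothelial score differed by -0.45 (adjusted p = 0.0844) and the smooth muscle and pericyte score by -0.41 (adjusted p = 0.0563). Scores of neutrophils (0.53, adjusted p = 0.0938), Schwann cells (-0.62, adjusted p = 0.124) and lymphocytes (-0.49, adjusted p = 0.124) had an unadjusted p under 0.05 as well. Of 24 adrenergic signalling components 9 rose and 1 fell over all genes, and 10 rose and 2 fell adjusted over the list alone (median 0.24, camera adjusted p = 0.044; adjusted p = 0.652 with an estimated correlation). Without Th-Cre saline DN2089 2 fell over all genes. The phosphodiesterase Pde3b stood at 0.59 ± 0.106 and the protein kinase A subunits Prkaca and Prkar1a both at 0.32.

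Brown adipocyte genes went both ways between the genotypes. Of 25 thermogenic and identity genes 4 rose and 4 fell over all genes, and 6 rose and 7 fell adjusted over the list alone (median 0.17, camera adjusted p = 0.857). The nuclear receptors Esrrg (0.98 ± 0.208) and Ppara (0.83 ± 0.195) rose, while Cox8b (-0.77 ± 0.13) and Cox7a1 (-0.52 ± 0.114) fell. Ucp1 fell too (-0.44 ± 0.126, adjusted p = 0.0136 by the edgeR quasi-likelihood test), with 3505 CPM ± 583 in Th-Cre and 4772 ± 782 in WT mice (SD, n = 6). Genes of glucose uptake and glycolysis had a median of 0.19 (camera adjusted p = 0.0591). Immediate early genes had a median of -0.28 (camera adjusted p = 0.188). Muscle transcripts were present in 3 of 6 Th-Cre and 1 of 6 WT saline libraries and had a median of 2.53 (camera adjusted p = 0.108). Library numbers of the genotypes do not mix, so a library batch and the genotype cannot be told apart, and no within-batch value can be given. Without the 6 libraries with muscle transcripts the count was 109 (57 higher, 52 lower; 100 of them among the 3270), and 33 of 48 calls on genes selected for naming were lost. Of 100 sets of 6 left-out libraries, that one included, the 11 without WT saline 2 gave 2116 to 3170 genes. The 89 with it gave 4 to 940, but most sets also left out muscle libraries. Sets that left out 0 muscle libraries of the saline groups gave 290 to 506 with WT saline 2 and 2646 without it. Without the muscle libraries the calls on Ube2ql1, Diaph1, Osbp, Ripk4, Nepn, Ndufa1, Myh11, Tagln and Cox8b stayed.

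With DCZ given to both genotypes, 1808 genes differed, 886 higher and 922 lower in Th-Cre mice, or 1938 (722 higher, 1216 lower) with upper-quartile factors. Ube2ql1 again led by p, with 24.7 CPM ± 18 (SD, n = 6) against 0.804 ± 0.65. The fitted rise was 30.6-fold (log2 fold change 4.93 ± 0.499 SE, adjusted p = 7.13e-06 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The transcription factor Irf4 was 6.44-fold higher (181 CPM ± 89.6 against 27.0 ± 14.6; 2.69 ± 0.377, adjusted p = 0.000183) and the nuclear envelope protein Syne3 3.26-fold (1.71 ± 0.193, adjusted p = 2.26e-05). Pdk4, which inhibits pyruvate dehydrogenase, was 2.01-fold higher (2378 CPM ± 341 against 1178 ± 184; 1.01 ± 0.115, adjusted p = 2.26e-05). All 6 Th-Cre DCZ libraries exceeded every WT DCZ library in these genes. For Pdk4 the saline libraries were apart as well, at 1381 CPM or more in Th-Cre and 1376 CPM or less in WT mice. Ffar4, a receptor of long-chain fatty acids, fell by 1.47 on the log2 scale (SE 0.241, adjusted p = 0.00101), Dlk1 by 2.22 (SE 0.358), Nnat by 2.71 (SE 0.54) and the lactonase Pon1 by 1.75 (SE 0.354).

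Among immediate early genes 16 of 28 were higher over all genes in Th-Cre than in WT mice given DCZ. Adjusted over the list alone 24 were higher and 1 lower (median 1.14, camera adjusted p = 9.14e-11, adjusted p = 0.497 with an estimated correlation). These are differences between genotypes, which a library batch cannot be told apart from, and not responses to DCZ. The immediate early score was also lower in WT DCZ (4.18 ± 0.525 SD, n = 6) than in WT saline libraries (4.52 ± 0.692, exact permutation p = 0.355). They included Nr4a1 (2.03 ± 0.346), Fos (1.85 ± 0.445), Jun (1.66 ± 0.224) and Dusp1 (1.15 ± 0.184). Of 21 acute cAMP and CREB targets 10 rose over all genes, and 12 rose and 1 fell adjusted over the list alone (median 0.58, camera adjusted p = 0.00159; adjusted p = 0.611 with an estimated correlation). Of 18 glucocorticoid responsive genes 4 rose over all genes and 8 adjusted over the list alone (0.33, camera adjusted p = 0.00233; adjusted p = 0.611 with an estimated correlation). Adrenergic components included the G protein regulator Rgs2 (1.09 ± 0.232), which rose, and Gnas (-0.65 ± 0.139), which fell. In that list 8 rose and 2 fell over all genes, and 11 and 2 adjusted over the list alone, while over all genes 5 rose without Th-Cre DCZ DN2097, and 5 rose and 1 fell without WT DCZ 5 (0.19, camera adjusted p = 0.0138; adjusted p = 0.497 with an estimated correlation). Adrb3 stood at 0.82 ± 0.224 (adjusted p = 0.0194 by the edgeR quasi-likelihood test), a call lost without WT DCZ 5 (0.78) or Th-Cre DCZ DN2097 (0.66). Lipid synthesis genes rose in 8 of 20 cases over all genes and 12 adjusted over the list alone (0.38, camera adjusted p = 0.00159; adjusted p = 0.611 with an estimated correlation). Over all genes 2 of these rose without WT DCZ 5, 3 without Th-Cre DCZ DN2097, 4 without WT DCZ 3 or 6 or Th-Cre DCZ DN2072 or DN2075, and 5 without Th-Cre DCZ DN2091. Nuclear oxidative phosphorylation fell in 20 of 36 over all genes and 32 adjusted over the list alone (-0.22, camera adjusted p = 8.56e-11; adjusted p = 0.497 with an estimated correlation). Over all genes 3 fell without WT DCZ 5, 6 without Th-Cre DCZ DN2075 or DN2097, 7 without WT DCZ 10 or Th-Cre DCZ DN2072, 14 with offsets for GC content and length (-0.19) and 1 without the muscle libraries (-0.23). Ribosomal protein transcripts took 0.811% ± 0.0821 (SD, n = 6) of the counts in Th-Cre and 0.997% ± 0.161 in WT DCZ libraries, and GC content and length accounted for 3.94% of the variance across genes. Ucp1 fell by 0.96 (SE 0.127, adjusted p = 0.000142 by the edgeR quasi-likelihood test), from 5395 CPM ± 721 in WT to 2808 ± 799 in Th-Cre mice (SD, n = 6). It was lower in 6 of 6 Th-Cre libraries than in any WT library. The thermogenic list had 1 risen and 6 fallen gene over all genes, and 2 and 8 adjusted over the list alone (camera adjusted p = 0.107). Without WT DCZ 1 or 6 it had 2 risen over all genes.

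Endothelial markers (-0.20, camera adjusted p = 0.0347; adjusted p = 0.711 with an estimated correlation) and smooth muscle and pericyte markers (-0.22, camera adjusted p = 0.0363; adjusted p = 0.611 with an estimated correlation) were lower under DCZ too by camera. Skeletal muscle markers, present in 2 of 6 Th-Cre and 0 of 6 WT DCZ libraries, had a median of 4.47 (camera adjusted p = 0.181). Without the 6 libraries with muscle transcripts the count was 535 (316 higher, 219 lower), and the calls on Scd1 (1.05), Elovl6 (0.80) and Gnas (-0.56) were lost. Counts also fell to 1081 in DCZ libraries alone. They were 850 without WT DCZ 5, 1174 without WT DCZ 10, 1026 without Th-Cre DCZ DN2072, 1133 without Th-Cre DCZ DN2075 and 1111 without Th-Cre DCZ DN2097.

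**Figure D4:**
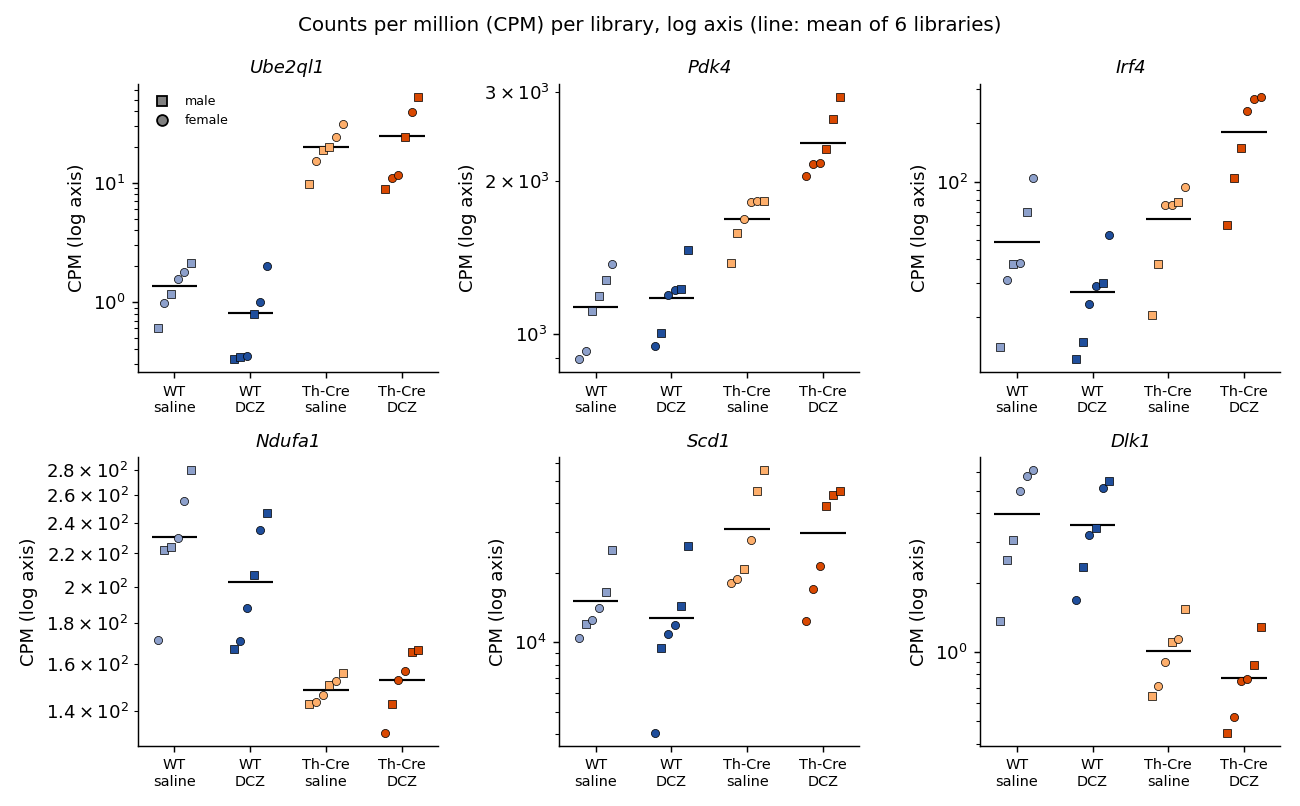
CPM (log axis) of Ube2ql1, Pdk4, Irf4, Ndufa1, Scd1 and Dlk1 in each library of the 4 groups (squares, males; circles, females; line, mean of 6 libraries). Ube2ql1 averages 1.37 CPM in WT saline and 20 CPM in Th-Cre saline libraries, and Pdk4 averages 1178 and 2378 CPM in WT DCZ and Th-Cre DCZ libraries.

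Both sexes were present in each group, which allows males and females to be compared over all 24 mice. There 1059 genes differed, 519 higher and 540 lower in males. Bmp8b, a secreted factor of brown fat (chromosome 4, 123105165 to 123132099, GRCm38), was 24.3-fold lower in males, with 0.243 CPM ± 0.253 against 5.96 ± 1.90 (SD, n = 12). Its log2 fold change was -4.61 ± 0.315 (SE, adjusted p = 4.04e-10 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The major urinary protein genes Mup18 (-4.74 ± 0.385) and Mup22 (-4.16 ± 0.346), which belong to a family of near-identical copies and so have uncertain counts, were lower as well. Gpam, which starts glycerolipid synthesis, fell by 0.57 (SE 0.0691, adjusted p = 1.22e-05), and the chemokine Cxcl14 rose by 0.76 ± 0.0946 (adjusted p = 1.64e-05). For these 5 genes no male library overlapped a female library. Y-linked transcripts were present in males at 63.5 CPM ± 4.84 for Eif2s3y, 48.6 ± 6.94 for Ddx3y, 13.8 ± 2.44 for Uty and 14.6 ± 2.40 for Kdm5d.

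Of the immediate early genes 10 of 28 rose over all genes in males and 15 adjusted over the list alone (median 0.46, camera adjusted p = 3.34e-08; adjusted p = 0.469 with an estimated correlation). Over all genes 4 rose without WT saline 9 or Th-Cre saline DN2087, 5 without WT saline 2 or WT DCZ 4, and 6 without WT saline 8, WT DCZ 10, Th-Cre saline DN2201 or Th-Cre DCZ DN2072 or DN2205. The list included Egr3 (1.56 ± 0.307), Fosb (1.68 ± 0.422), Junb (0.98 ± 0.254) and Gadd45b (0.99 ± 0.223). Inflammatory and NF-kB targets had a median of 0.40 (camera adjusted p = 0.00303; adjusted p = 0.531 with an estimated correlation). Of 19 secreted factors of adipose tissue 4 fell and 2 rose over all genes, and 6 and 2 adjusted over the list alone (-0.26, camera adjusted p = 0.00954; adjusted p = 0.126 with an estimated correlation). The adipsin gene Cfd fell (-0.96 ± 0.186). Of 25 thermogenic and identity genes 5 fell and 1 rose over all genes, and 8 fell and 1 rose adjusted over the list alone (-0.13, 0.00954; adjusted p = 0.549 with an estimated correlation). Among them were the fatty acid elongase Elovl3 (-0.89 ± 0.154), creatine kinase Ckb (-0.76 ± 0.159) and Ucp1 (-0.33 ± 0.0889). Glucose uptake and glycolysis genes fell in 3 of 20 cases (5 without WT saline 12, 6 without WT DCZ 6), and 5 adjusted over the list alone, as with Pfkp (-0.50 ± 0.108) and Hk1 (-0.40 ± 0.0978; list median -0.12, camera adjusted p = 0.00662; adjusted p = 0.469 with an estimated correlation). The heat shock list, with Hspa8 at -0.38 ± 0.0771, had a median of -0.23 (camera adjusted p = 0.00954; adjusted p = 0.531 with an estimated correlation). Scd1 rose by 0.92 ± 0.193 and Dcn, a matrix proteoglycan, by 0.58 ± 0.0876.

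Skeletal muscle markers had a median of -3.41 in males, with 9 of 13 fallen over all genes and 13 adjusted over the list alone (camera adjusted p = 0.00662; adjusted p = 0.968 with an estimated correlation), and 4 of the 6 libraries that contain muscle came from females. Over all genes 1 fell without Th-Cre saline DN2094, 2 without WT saline 12, Th-Cre saline DN2099 or Th-Cre DCZ DN2075, 3 without Th-Cre DCZ DN2072 or Th-Cre saline DN2089, 4 without WT saline 7 or 11, and 5 without WT saline 9 or Th-Cre DCZ DN2097. Without the 6 libraries that median was 0.69 over the 4 markers still tested. In that setting 836 genes differed between the sexes and the call on Scd1 (0.79) was lost.

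**Figure D5:**
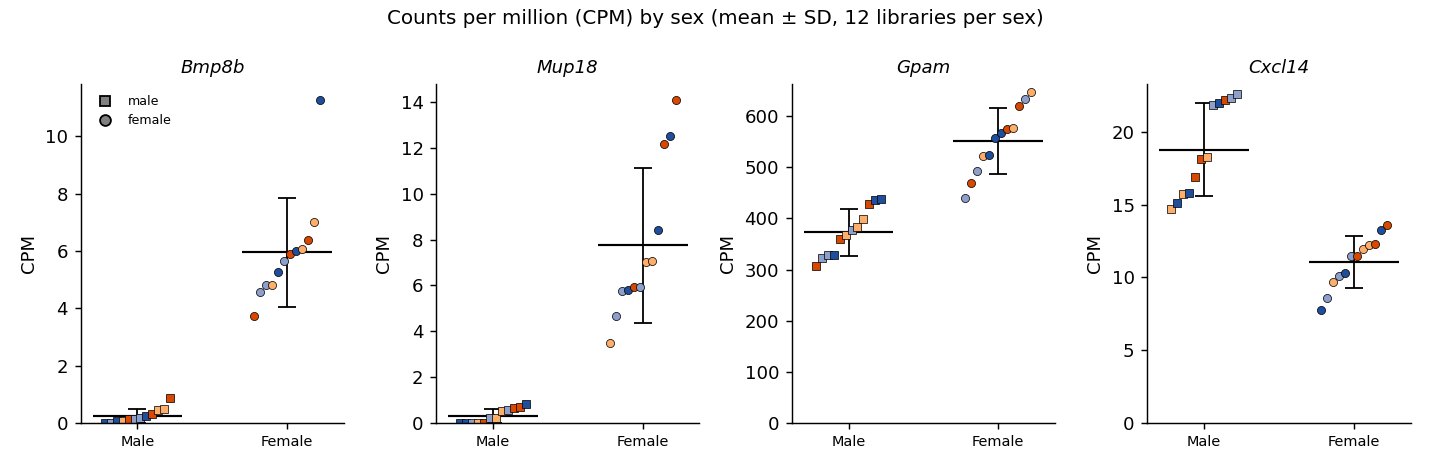
CPM of Bmp8b, Mup18, Gpam and Cxcl14 by sex over 24 libraries (squares, males; circles, females; light and dark blue, WT saline and DCZ; light and dark orange, Th-Cre saline and DCZ; line and bar, mean ± SD of 12 libraries). Bmp8b averages 0.243 CPM in males and 5.96 CPM in females.

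Whether DCZ acted differently in males and females was tested within each genotype, with 3 mice of each sex per group. In Th-Cre mice 0 genes passed the edgeR quasi-likelihood test (903 with an unadjusted p under 0.05), while DESeq2 called 19. The smallest adjusted p, 0.0826, was that of the adaptor protein Bcar3 (-1.21), the stress-induced transcription factor Ddit3 (1.18), Ypel2 (-0.82) and Inip (0.99). Heat shock genes had a positive difference in 14 of 15 cases (median 0.34, camera adjusted p = 7.24e-05; adjusted p = 0.16 with an estimated correlation). Fibroblast and preadipocyte markers had a median of -0.41 (0.00177; adjusted p = 0.834 with an estimated correlation). By edgeR 0 members of either list were past the test over all genes or adjusted over the list alone. Leaving out Th-Cre saline DN2201 gave 15 genes and leaving out Th-Cre DCZ DN2091 gave 1. In WT mice 0 genes passed as well (328 with an unadjusted p under 0.05; DESeq2 called 1), and mitochondrially encoded mRNAs had a median difference of 0.35 with 13 of 13 positive (camera adjusted p = 0.000361; adjusted p = 0.782 with an estimated correlation).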

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

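The tests of DCZ without Cre, of handling, of library batch, of nerve share and of a receptor transgene were chosen after the result was seen, and leaving out libraries with muscle transcripts, the draws of left-out libraries, the muscle covariate and the GC and length offsets were added after seeing the data. Random splits of the libraries were planned, and 100 were drawn for each result with the real one included.

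Single libraries stood far from the 5 others of their group in 4 of 120 groups examined over 30 measures, and chance does this in about 1 in 20 groups. The skeletal muscle score of WT saline 12 was 4.25 against -2.07 to -1.07 in the others, and that of WT DCZ 1 was 0.0884 against -1.75 to -1.18. The lymphocyte score of WT DCZ 3 was 0.950 against -0.333 to 0.137. The log2 CPM of Jun in Th-Cre saline DN2087, which also contains muscle transcripts, was 6.89 against 5.5 to 5.80.

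Responses that differed between the genotypes were Arl4d (interaction log2 value 1.53) and the immediate early score, whose difference between DCZ and saline was 1.17 higher in Th-Cre than in WT mice. By camera with a preset correlation, 7 lists differed: immediate early genes (median 1.35), acute cAMP and CREB targets (0.50), thermogenic and brown adipocyte identity genes (-0.16), glucocorticoid responsive genes (0.44), inflammatory and NF-kB targets (0.76), endothelial markers (0.24) and Schwann cell markers (0.57). The DCZ response differed between the sexes in Th-Cre mice for heat shock genes (0.34) and fibroblast and preadipocyte markers (-0.41), and in WT mice for mitochondrially encoded mRNAs (0.35). None of these 10 list calls held with an estimated correlation.

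The higher immediate early scores of Th-Cre DCZ libraries were weighed against technical sources. The score changed by 0.82 in Th-Cre and by -0.34 in WT mice, and the exact two-sided test of the difference over 853776 arrangements gave p = 0.0132, but with WT libraries exchanged only within the lower 6 and the upper 6 library numbers, which treatment nearly follows, the WT difference was -0.23 and the exact p = 0.0679, so DCZ acting without Cre cannot be told apart. Muscle in some libraries is argued against as the whole source, since the score difference without those libraries was 1.08 ± 0.259 (SE; 4 against 3 libraries). The exact permutation p of that difference was 0.0571 over 35 arrangements, so chance is not excluded for it. Handling or time to dissection cannot be told apart, since 5 of 12 saline libraries (4 WT and 1 Th-Cre) reached the lowest Th-Cre DCZ score of 4.5 and the sources used here give no order of dissection. Activity of sympathetic neurons may raise these genes, a hypothesis that was not itself tested here.

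The 3270 genes that differed between Th-Cre and WT saline libraries were weighed next. GC content and transcript length are argued against as the whole source, since 3136 genes were called with offsets for both and 2664 of these were among the 3270. Muscle is argued against as the whole source, since 2926 genes were called with the muscle score as a covariate (2754 shared). Without the 6 libraries 100% of the 3270 had the same sign at a median fold ratio of 0.944. These genes were chosen with the libraries that stay, so that agreement is partly built in and decides nothing by itself. The count without the muscle libraries was 109, where the median SE was 0.133 in place of 0.102. Among 100 sets of 6 left-out libraries, that set included, the 11 without WT saline 2 called 2116 to 3170 genes. The 89 that kept it called 4 to 940 (median 86), and 50 of these, that set included, called 109 or fewer. Most sets also left out muscle libraries, so they do not show what the loss of other libraries gives. Sets that left out 0 muscle libraries of the saline groups called 290, 387, 393 and 506 genes with WT saline 2, and 2646 without it. Muscle as a source of part of the calls thus stays open. A library batch may be the source and cannot be told apart from genotype, since 0 Th-Cre libraries are among the first 12 library numbers, and strain background, housing and Cre itself stay open as untested.

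Chance is unlikely for the 3 genes of Th-Cre DCZ against saline, where 2 of 100 splits gave as many as 3. It is not excluded, since the highest other split gave 26. That split put all 5 Th-Cre libraries with muscle transcripts on the same side, but whether muscle made its calls was not tested. For the single gene in WT the share was 2 of 100, but the highest other split, of WT 1, 2, 3, 4, 6 and 7 against 5, 8, 9, 10, 11 and 12, called 1370 genes, which points to a structure of the WT libraries that goes with the order of their numbers. For the single interaction gene chance cannot be excluded, with 7 of 100 splits as large and 86 genes in the highest other.

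Chance is unlikely for Th-Cre against WT under saline (3270 genes, 1 of 100 splits as large, the fewest that 100 splits can give). There the highest other split gave 2262. Apart from the names of the groups, its saline groups differed from the real ones only by the exchange of WT 2 and Th-Cre DN2086. Its DCZ groups likewise differed by the exchange of WT 4 and Th-Cre DN2075. Chance is also unlikely for the genotypes under DCZ (1808 genes, 1 of 100, highest other 8) and for male against female mice (1059 genes, 1 of 100, highest other 1). For the sex and DCZ interactions the edgeR test gave 0 genes, which any split equals or exceeds (100 of 100), so the splits decide nothing about chance there. The highest other split called 108 genes in Th-Cre mice (real split 903 genes with an unadjusted p under 0.05, 19 by DESeq2) and 99 in WT mice (328 and 1). Such splits call more genes than the real split. They exchange sex labels within each group, which can carry the difference between males and females into this contrast. They therefore do not show a structure beyond sex and treatment. Chance cannot be excluded for the numbers of called lists, with 7 in Th-Cre DCZ against saline (42 of 100 splits as large, highest other 14) and 7 in the interaction (32 of 100, highest other 12). For the immediate early list itself chance is unlikely, with a camera p of 1.34e-27 against 4.92e-21 in the best other split. The real split was thus 1 of 100, the fewest that 100 splits can give. Since 70 of the 100 splits gave this list a camera p under 0.05, that p cannot be read at face value.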

How the results depend on the processing

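Counts of changed genes moved with several settings. In Th-Cre mice, 3 genes became 20 without a filter, 7 with a stricter filter, 5 with a robust fit, 13 in Th-Cre libraries alone, 15 in females alone, 37 by DESeq2, 12 by limma-voom, 14 with the authors' normalized values, 7 without the 6 libraries with muscle transcripts and 8 with the muscle covariate. In WT mice the 1 gene became 0 without a filter, with a stricter filter, without the sex term, in WT libraries alone, in males or females alone, with the authors' normalized values and without the muscle libraries, 2 by DESeq2 and 3 by limma-voom. The 1 interaction gene became 8 without a filter, 0 with a stricter filter, which removes Arl4d, 2 without the sex term, 16 by DESeq2, 2 by limma-voom, 4 without the muscle libraries and 2 with GC and length offsets. Without the muscle libraries 109 of 3270 genes were called between genotypes under saline and 535 of 1808 under DCZ, where the compared groups alone gave 1081. For the sex and DCZ interaction, Th-Cre mice had 5 genes without a filter and 19 by DESeq2, and WT mice had 1 by DESeq2. Leaving out each library in turn gave 3 to 18 genes in Th-Cre DCZ, 0 to 39 in WT DCZ, 1 to 7 in the interaction, 2349 to 4270 and 850 to 2443 between genotypes under saline and DCZ, 790 to 1162 between sexes, and 0 to 15 (Th-Cre) and 0 to 0 (WT) in the sex and DCZ interaction. The cause was not tested except where stated.

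With an estimated correlation 0 lists were called in each of the 8 comparisons, against 7 in Th-Cre DCZ, 4 in WT DCZ, 7 in the interaction, 5 and 8 between genotypes under saline and DCZ, 8 between sexes, and 2 (Th-Cre) and 1 (WT) in the sex and DCZ interaction. By fry there were 1 in Th-Cre DCZ, 0 in WT DCZ, 0 in the interaction, 5 and 4 between genotypes under saline and DCZ, 5 between sexes and 0 in both sex and DCZ interactions. Without the muscle libraries there were 2 in WT DCZ and 9 between genotypes under saline. Between sexes, muscle genes, whose calls were lost without Th-Cre saline DN2094, turned to positive log2 values with the muscle covariate, a mean over markers that include Myh1, Atp2a1, Ckm and Acta1, so that such a loss or turn is largely built in: Myh1 0.99, Atp2a1 0.55, Actn3 0.49, Ttn 0.72, Ckm 0.40 and Acta1 0.87, and Acta1 had 1.46 without the muscle libraries. Of 5100 pairs of a named gene and a setting, 4721 kept their side of the threshold (13 of these, called in neither setting, changed sign), 275 fell short of it, 97 passed it and 7 turned. At the depth used, Th was not detectable, and simulated interactions of sex and DCZ found 14.9% (Th-Cre) and 10.4% (WT) of genes changed 1.5-fold.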

Other observations

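The genes named in the next paragraph on immune transcripts were selected by the planned rule, and the tests of nerve share and of a receptor transgene were chosen after the result was seen.

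Igha, Igkc and Jchain, genes of antibodies and their assembly, were higher in Th-Cre than in WT saline libraries, and no list of such genes was tested. The call on a B cell transcript in the other direction rests on single libraries. In Th-Cre saline libraries Igha, the constant region of IgA, averaged 34.6 CPM ± 27.5 (SD, n = 6) against 0.0715 ± 0.094 in WT (adjusted p = 6.15e-05 by the edgeR quasi-likelihood test), with 6 of 6 Th-Cre libraries above every WT library. The light chain Igkc was 7.73-fold higher (log2 fold change 2.95 ± 0.638 SE, adjusted p = 0.00303) and Jchain, which joins antibody units, 7.68-fold (2.94 ± 0.603, adjusted p = 0.00239). The B cell receptor subunit Cd79b fell by 1.29 (adjusted p = 0.0436). The call on Cd79b was lost without any 1 of WT saline 2, 8, 9, 11 and 12 and Th-Cre saline DN2099, DN2087, DN2094, DN2086 and DN2089 (-1.40 to -1.04).

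Mitochondrially encoded mRNAs did not move as a set between the genotypes under saline (median -0.14, camera adjusted p = 0.59). mt-Nd3 fell by 0.64 (SE 0.113, adjusted p = 0.00122 by the edgeR quasi-likelihood test) and mt-Nd5 rose by 0.56 (SE 0.168, adjusted p = 0.0179). Between the sexes, mast cell markers had a median of -1.29 in males (camera adjusted p = 0.0304; adjusted p = 0.469 with an estimated correlation), as with the protease Cma1 (-1.61 ± 0.367 SE).

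Chrm3, the muscarinic receptor gene from whose human version a DCZ-activated receptor is built, had 301 reads over the 12 Th-Cre libraries and 18 over the 12 WT libraries. A larger share of nerve in Th-Cre tissue is argued against as its source as far as 9 tested nerve markers tell. These were 1 of sympathetic neurons and 8 of Schwann cells (17 listed, 0 in another list). They had a median log2 fold change of -0.61 in Th-Cre against WT saline libraries and a highest value of 0.01. Under DCZ the Schwann cell score was 2.35 ± 0.570 in Th-Cre and 2.30 ± 0.508 in WT libraries (SD, n = 6). With 1 of 9 sympathetic neuron markers tested, the share of sympathetic nerve itself stays open. A human muscarinic receptor transgene could be the source, in nerves too, and cannot be told apart from the mouse gene by counts per gene, with 11 of 12 Th-Cre libraries above the highest WT library (0.266 CPM on total counts), while the other lay at 0.262. A state of the adipocytes that also sets lipogenic genes cannot be told apart either. Over the 12 Th-Cre libraries Chrm3 had a Pearson r of 0.165 with the fatty acid and triglyceride synthesis score (permutation p = 0.611) and a Spearman rho of 0.0280 (permutation p = 0.939). That r was -0.0408 without the 2 libraries farthest from the median and 0.20 within groups.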
